A study of Rattus norvegicus with 6 samples.

How the data were processed

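Small RNA libraries were made from 1 µg of total RNA per serum exosome sample, extracted with Trizol, using the NEBNext small RNA kit, and sequenced as single-end 50 bp reads on an Illumina HiSeq, per the labels' protocols. The submitters' processing notes name FastQC, BWA, edgeR and the rat build rn6, without versions, roles or order, and adapter trimming, alignment settings and the miRNA annotation release are not given in the sources used here. One deposited table of 763 mature miRNAs was used, with 6 library columns and the authors' log2 fold change and unadjusted p-value, per the file headers.

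The deposited library columns hold a normalised signal and not whole read counts. Their values follow the form of counts moved by quantile adjustment to a common library size of 265919, with a common negative binomial dispersion of 0.503 and rows without counts at a tiny constant, a form that the edgeR package named in the submitters' processing notes writes. This was worked out from the values, since no label or header states it. The adjustment was inverted separately within each group, since this form moves counts around the group means. It used 4 parameters fitted to 9 control values, and a size ratio for each IPC library fitted to IPC values. Of the 4578 values, 4578 (100%) came out within 0.01 of a whole count. Recomputed values differed from the deposited ones by at most 1.0e-08 in relative terms, and the product of the 6 effective library size ratios, which was not fixed in the fit, came out at 1.00. A trimmed mean of M values (log ratio trim 0.3, abundance trim 0.05) computed on the recovered counts gave the same scaling factors, from 0.783 in control replicate 1 to 1.41 in control replicate 2. Given the true size ratios and dispersion, the inversion returned 2880 of 2880 counts in a simulated data set. The fitting of those parameters was not part of that simulation.

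The design written before the data were examined planned a count model. Because the deposited values are not counts, the main test was the one that the design named for normalised values, limma (version 3.58.1, R 4.3.3, trended and robust empirical Bayes) on log2(value + 1), with the group as its only term and all 6 libraries, and Benjamini-Hochberg adjustment over the miRNAs tested. Fold changes are on the log2(value + 1) scale, which understates the change of low miRNAs. Tested miRNAs had at least 10 counts at the median effective library size, which is 34.9 CPM (counts scaled to a common library size), in at least 3 libraries, and at least 15 counts in all. The adjusted p threshold was 0.05. limma-voom, with and without sample quality weights, was the only model run on the recovered counts. Depth per library ran from 111048 to 762927 counts. Count floors (3 counts) and intervals cover counting error only, since the reads carry no molecular identifiers.

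Samples were grouped by the treatment in the labels, 3 IPC and 3 control. All pairs of libraries within a group differed by far more than sampling noise (chi-square over degrees of freedom 150 to 445), and each was counted as 1 replicate. Technical differences between libraries could give such ratios too, so they do not show separate rats. The replicate numbers in the titles were not used to pair samples.

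Lists of 117 memberships in 13 lists were fixed before the data were examined, for muscle, red cells, platelets, leukocytes, liver, endothelium and vessels, the let-7 family, the miR-17-92 cluster and paralogs, hypoxia and ischemia, fibrosis, neurons, epithelium and pancreas, and the Dlk1-Dio3 locus. Some miRNAs are in more than 1 list, such as miR-133a-3p and miR-24-3p. Lists with at least 3 tested members were tested with camera (inter-gene correlation 0.01), with camera using an estimated correlation, and with fry, each adjusted over the 13 lists. Named miRNAs were every measured arm of miR-133a and miR-133b, the 6 with the smallest unadjusted p per direction (as values, since fewer than 5 passed the adjusted threshold), the 10 with the highest mean CPM, and, per list, members passing adjusted over the list alone (at most 4) and the 2 most abundant. miR-208a-3p and miR-499-5p fall outside that rule and were named after their values were seen, to complete the muscle list. miR-1b and miR-223-3p also fall outside it and were named after their values were seen.

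Shares of counts and numbers of detected miRNAs were compared by exact permutation tests over the 20 assignments of the 6 libraries, whose smallest two-sided p is 0.1. Neighbouring miRNA genes were taken from a RefSeq gene table of assembly GRCr8, used for names and neighbours alone since the authors' build differs. It matched 217 of the 219 tested miRNAs outside the muscle list. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

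The pipeline was tested on 20 simulated data sets with the real means, library sizes and common dispersion, for the comparison of 3 IPC with 3 control libraries. limma at an adjusted p below 0.05 recovered 24.5% of 384 miRNAs changed 4-fold, 64.7% of 139 changed 8-fold and 91.6% of 392 changed 16-fold, with a mean of 222.3 miRNAs tested per set. Of calls in the simulations, 3.91% on average were unchanged miRNAs, and 6.2% of unchanged miRNAs had an unadjusted p below 0.05. camera called the simulated muscle list in 20 of 20 sets. The simulated miRNAs were drawn independently, so these rates leave out correlation between miRNAs. The real muscle list had an estimated correlation of 0.53, under which its camera call was lost.

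Alternatives planned before the data were examined were other scalings (median-of-ratios size factors, library totals, upper quartile, and trimmed mean of M values without the 10 most abundant miRNAs), no filter, a filter at 10 CPM, pseudocounts of 0.1 and 10, a replicate block, leaving out each library, other thresholds, and the list tests above. Thinning the counts to the smallest library, the first principal component as a covariate, the muscle list as 1 value per library, 100 repeated thinnings with fixed scaling factors, lists without the miR-133 arms, and the pseudocounts for lists and miR-133a-3p were added after seeing the data. Sequence composition was not analysed here, since no miRNA sequences were used.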

Results

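MicroRNAs (miRNAs) were profiled by small RNA sequencing in exosomes, the small vesicles that cells release into blood, isolated from the serum of adult male Sprague-Dawley rats aged 9 to 10 weeks and weighing 250 to 280 g. The IPC group held 3 samples, taken after ischemic preconditioning, in which the left anterior descending coronary artery was closed and reopened in 3 cycles of 5 min of ischemia and 5 min of reperfusion. The control group held 3 samples of blood drawn without preconditioning, and the labels describe no sham operation for it. They also do not say whether the samples of a group came from separate rats, so the p-values measure the spread between these samples, which may be technical. Counts recovered from the deposited values summed to 111048, 152343 and 129728 in control replicates 1, 2 and 3, and to 762927, 661405 and 319285 in IPC replicates 1, 2 and 3. Every IPC library was deeper than every control library, with a mean total 4.44 times as high (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 samples allow). Of the 480 miRNAs with a count in any library, 226 passed the abundance filter and were tested.

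**Figure D1:**
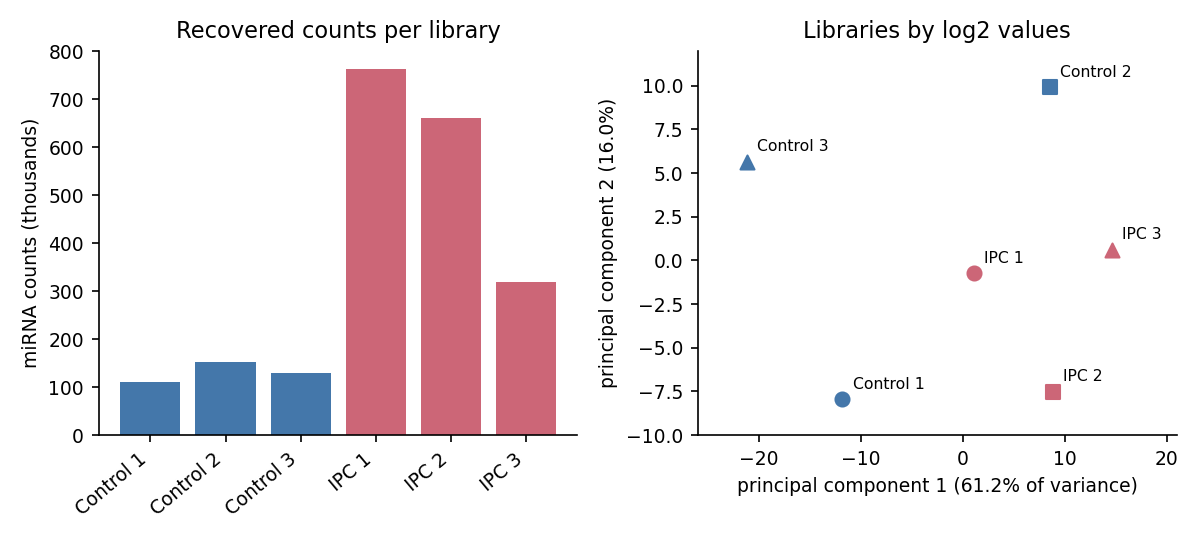
Left, recovered miRNA counts (bars, axis from 0) for each library. Right, the 6 libraries on the first 2 principal components of the log2 values, with percent of variance on the axes. Control replicate 2 lies at 8.52 on the first component, among the IPC libraries (1.08 to 14.6), and the other controls lie at -11.8 and -21.2.

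The comparison of IPC with control samples asks which exosomal miRNAs differ after preconditioning, and the series title names miR-133a-3p. In limma the 3 highest log2 fold changes among the tested miRNAs were those of the muscle miRNAs miR-206-3p, miR-1-3p and miR-133a-5p. miR-206-3p, which is made in skeletal muscle, was at 987 ± 905 normalised counts after IPC and 45.5 ± 51.7 in controls (mean ± SD, n = 3 each), a log2 fold change of 4.49 (SE 1.01) or 22.5-fold. It was 3.80 without control replicate 1, 5.41 without control replicate 2, 5.39 without IPC replicate 1 and 3.72 without IPC replicate 2. miR-1-3p, abundant in heart and skeletal muscle, was at 6636 ± 5638 and 705 ± 1092, a log2 fold change of 4.36 (SE 1.25). It was 3.69, 5.94 and 3.46 without control replicate 1, 2 or 3, and 5.31 and 3.64 without IPC replicate 1 or 2. miR-133a-3p, made from the same transcripts as miR-1, was at 3765 ± 2904 and 686 ± 231, a log2 fold change of 2.25 (SE 0.69) or 4.75-fold (1.66 without IPC replicate 2), and each IPC library lay above each control library.

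Of the 8 members of the muscle list fixed before the data were examined, 7 were tested, and all 7 rose in the test adjusted over the list alone, while 0 passed when adjusted over all 226 miRNAs (limma, smallest adjusted p = 0.212). miR-1b, tested but outside that list, had 117, 237 and 90 recovered counts in control replicates 1, 2 and 3. It had 174, 2236 and 866 in IPC replicates 1, 2 and 3. IPC replicate 1, the deepest library, thus had fewer than control replicate 2. These counts are not scaled to depth, so they show no rise by themselves. The effective library size ratios were 0.327, 0.808 and 0.438 in control replicates 1, 2 and 3. They were 2.68, 2.39 and 1.35 in IPC replicates 1, 2 and 3, so after scaling IPC replicate 1 lay below each control. The list as a set ranked above the other miRNAs (limma camera, adjusted p = 2.5e-06). That call was lost with an estimated correlation (adjusted p = 0.68). fry, which tests a list against no change and not against the other miRNAs, gave an adjusted p = 0.277 (unadjusted 0.0213). miR-133b-3p was at 770 ± 578 and 154 ± 59.2 normalised counts, a log2 fold change of 2.16 (SE 0.74). It differs little in sequence from miR-133a-3p, so the division of reads between these paralogs is uncertain. miR-208a-3p is encoded in a myosin gene of the atria and the adult rodent ventricle, and miR-499-5p in another myosin gene. They are called heart miRNAs here, though whether miR-499-5p stands for heart alone was not tested. In control replicates 1, 2 and 3 they rested on 4, 76 and 1 and on 6, 126 and 2 recovered counts. Their log2 fold changes were 2.83 (SE 1.03) and 2.82 (SE 1.03). Without control replicate 2 these were 4.05 and 4.08, and without control replicate 3 they were 1.76 for each. miR-133a-5p had a log2 fold change of 3.50 (SE 0.92) that rested on 3 counts in all controls and 220 in all IPC libraries, a ratio of 18.0 after scaling (exact 95% interval 6.07 to 87.8, counting error only). miR-133b-5p had 0 control counts and 1 IPC count, at or under the floor of 3 counts, and no fold is given. The title names miR-133a-3p, presumably from these samples, so its direction and its share in the list are not independent evidence. Over the 4 other tested members the adjusted p was 0.00182 in camera at the fixed correlation of 0.01, and with an estimated correlation the unadjusted p was 0.101, so that call too was lost.

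Control replicate 2 stood nearer the IPC libraries than the other controls did, with 1966 normalised counts of miR-1-3p against 86.9 and 62.4 in control replicates 1 and 3 and 1235 to 12485 in the IPC libraries. Its Spearman correlation over the 226 tested miRNAs, which are not independent replicates, was 0.93 with IPC replicate 3 and 0.77 and 0.69 with the other controls. Control replicate 1 also correlated highest with an IPC library, at 0.88 with IPC replicate 1 against 0.86 with control replicate 3. The number of muscle miRNAs passing adjusted over the list alone was 4 without control replicate 3 and 1 without IPC replicate 2. Muscle miRNAs took 4.71% ± 3.54 of all counts after IPC and 0.779% ± 0.914 in controls (SD, n = 3 each; exact permutation test, two-sided, p = 0.2). The shares were 1.43%, 8.46% and 4.25% in IPC replicates 1, 2 and 3, and 0.285%, 1.83% and 0.217% in control replicates 1, 2 and 3.

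**Figure D2:**
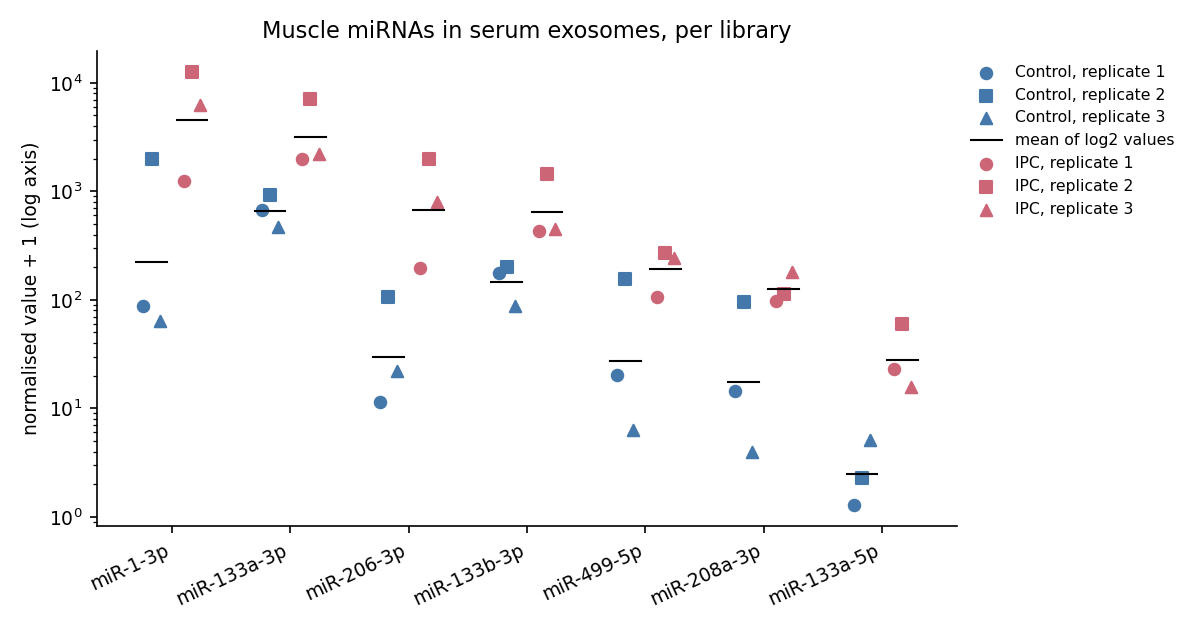
Normalised value + 1 on a log axis for the 7 tested muscle miRNAs, one point per library (blue, control; red, IPC; the marker gives the replicate number), with black lines at the group means of the log2 values. miR-206-3p is at 194 to 1973 in the IPC libraries and 10.4 to 105 in the controls.

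Over all 226 miRNAs, the muscle miRNAs included, limma called 0 higher and 0 lower at an adjusted p below 0.05, and 20 higher and 4 lower at an unadjusted p below 0.05, where 11.3 of 226 are given by chance. limma-voom on the recovered counts also called 0, with 19 higher and 4 lower at an unadjusted p below 0.05. Without control replicate 2, 29 miRNAs were called higher and 9 lower, among them all 7 muscle miRNAs. All IPC libraries lay above all controls for 28 miRNAs and below for 3, which is 13.7% of those tested against the 10% that chance gives. Of the 226 log2 fold changes 142 were positive, with a median of 0.38. Scaling by median-of-ratios size factors shifted that median by -0.24, and the counts at an unadjusted p below 0.05 were then 12 higher and 7 lower.

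The other values with the smallest unadjusted p did not pass the adjusted threshold. miR-872-5p was at 318 ± 112 normalised counts after IPC and 75.5 ± 21.6 in controls, and miR-362-3p at 45.2 ± 13.8 and 8.90 ± 7.41 (n = 3 each). Their log2 fold changes were 2.04 (SE 0.65) and 2.46 (SE 0.78), both with an adjusted p = 0.341 (limma). On the lower side, miR-3473 was at 332 ± 193 after IPC and 1541 ± 925 in controls, a log2 fold change of -2.26 (SE 0.76), with all IPC libraries below all controls. miR-193a-5p had a log2 fold change of -1.89 (SE 0.73), miR-204-3p of -2.25 (SE 0.94), miR-27a-5p of -1.52 (SE 0.71) and miR-671 of -1.78 (SE 0.86). miR-320-3p, among the 10 most abundant miRNAs, was at 10716 ± 4894 after IPC and 42752 ± 27973 in controls, a log2 fold change of -1.76 (SE 0.73) with an adjusted p = 0.35 (limma). Without control replicate 2, these passed the adjusted threshold except miR-3473, miR-27a-5p and miR-671, with log2 fold changes of 2.19 for miR-872-5p, 3.04 for miR-362-3p, -2.35 for miR-193a-5p, -2.97 for miR-204-3p and -2.54 for miR-320-3p. miR-204-3p was at -1.64 without control replicate 3, -2.97 without IPC replicate 1 and -1.67 without IPC replicate 3. miR-671 was at -2.42 without control replicate 2 and -1.13 without control replicate 3, and miR-3473 at -1.65 without IPC replicate 3.

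Besides the muscle list, camera called 2 lists. The fibrosis-related list, which holds miR-29 family members that target collagen mRNAs, had 9 of 9 tested members with positive log2 fold changes (median 1.51, adjusted p = 0.00945), and 0 members passed adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.914), and fry, against no change, gave an adjusted p = 0.278 (unadjusted 0.0652). Its mean of 1.55 was 2.14 without control replicate 2, and 1.13 at the lowest with a library left out. Over the alternatives that keep all libraries its lowest mean was 0.65. With the first principal component as a covariate the camera call was also lost (adjusted p = 0.431). The list shares miR-133a-3p with the muscle list, and without it the adjusted p was 0.027, or 0.238 unadjusted with an estimated correlation. miR-24-3p, its most abundant member, was at 17701 ± 3584 normalised counts after IPC and 11525 ± 5407 in controls. miRNAs of the miR-17-92 cluster and its paralogs, which are expressed in dividing cells, had 8 of 8 tested members positive (median 1.54, adjusted p = 0.018). This call was lost with an estimated correlation (adjusted p = 0.914), and also without control replicate 2 (adjusted p = 0.0883), control replicate 3 (0.218) or IPC replicate 3 (0.0678). The list mean of 1.57 was 0.78 without control replicate 3. Fry, against no change, gave an adjusted p = 0.354 (unadjusted 0.136). In this list miR-92a-3p had a log2 fold change of 1.13 (SE 0.70) and miR-25-3p of 0.54 (SE 0.58).

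The markers of blood cells and other tissues did not pass camera (adjusted p = 0.758 to 0.81 over 10 lists). Positive log2 fold changes were found for 3 of 6 red-cell, 7 of 8 platelet, 6 of 8 leukocyte, 3 of 4 liver and 7 of 8 endothelial and vascular miRNAs. They were found for 7 of 8 let-7 family, 2 of 5 hypoxia and ischemia, 1 of 3 neural, 4 of 5 epithelial and pancreatic and 5 of 7 Dlk1-Dio3 locus miRNAs. The medians were -0.023 for red-cell, 0.66 for platelet, 0.78 for leukocyte, 0.28 for liver, 0.53 for endothelial and vascular, 0.56 for let-7, -0.00024 for hypoxia and ischemia, -0.015 for neural, 0.61 for epithelial and pancreatic and 0.42 for Dlk1-Dio3 locus miRNAs. For red-cell and hypoxia miRNAs the mean was positive (0.25 and 0.16) where the median was not, and for these and liver camera, which ranks a list against the other miRNAs, gave the downward direction. miR-486 and miR-451-5p, abundant in red cells, had log2 fold changes of 0.11 (SE 0.59) and -0.69 (SE 0.60), and the first turns negative under 3 of the 4 other scalings. Red-cell miRNAs took 5.38% ± 0.452 of counts after IPC and 5.68% ± 1.91 in controls (exact permutation test, two-sided, p = 0.9). In the leukocyte list miR-142-5p was at 2557 ± 315 and 1158 ± 164 normalised counts and miR-146a-5p at 2770 ± 1515 and 1677 ± 715. miR-223-3p, in both the platelet and the leukocyte list, was at 1125 ± 559 and 324 ± 153, with all IPC libraries above all controls. Its log2 fold change was 1.78 (SE 0.72; limma, unadjusted p = 0.0296, adjusted p = 0.35). It was the only member of either list at an unadjusted p below 0.05. miR-122-5p, a miRNA of hepatocytes, had a log2 fold change of -0.72 (SE 0.63), and miR-210-3p, induced by hypoxia, of -0.82 (SE 0.81). miR-126a-3p of endothelium had 0.17 (SE 0.76), negative under 2 of the 4 other scalings, miR-143-3p of smooth muscle 0.66 (SE 0.64) and miR-21-5p 0.79 (SE 0.77). Among the remaining lists, log2 fold changes were -1.30 (SE 0.83) for let-7b-5p, -0.75 (SE 0.90) for miR-129-5p, -0.47 (SE 0.70) for miR-375-3p, 1.36 (SE 0.82) for miR-203a-3p, -0.17 (SE 0.62) for miR-134-5p and 0.42 (SE 0.85) for miR-127-3p. Without control replicate 2, miR-203a-3p passed the adjusted threshold at 2.22, and let-7b-5p was at -1.92, miR-21-5p at 1.53 and miR-210-3p at -1.57. Without control replicate 3 the values were 0.67 for miR-203a-3p, -0.30 for let-7b-5p, 0.18 for miR-21-5p and 1.11 for miR-127-3p. miR-127-3p was at -0.17 without control replicate 1, miR-129-5p at 0.050 without IPC replicate 3 and miR-126a-3p at 0.80 without IPC replicate 1.

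**Figure D3:**
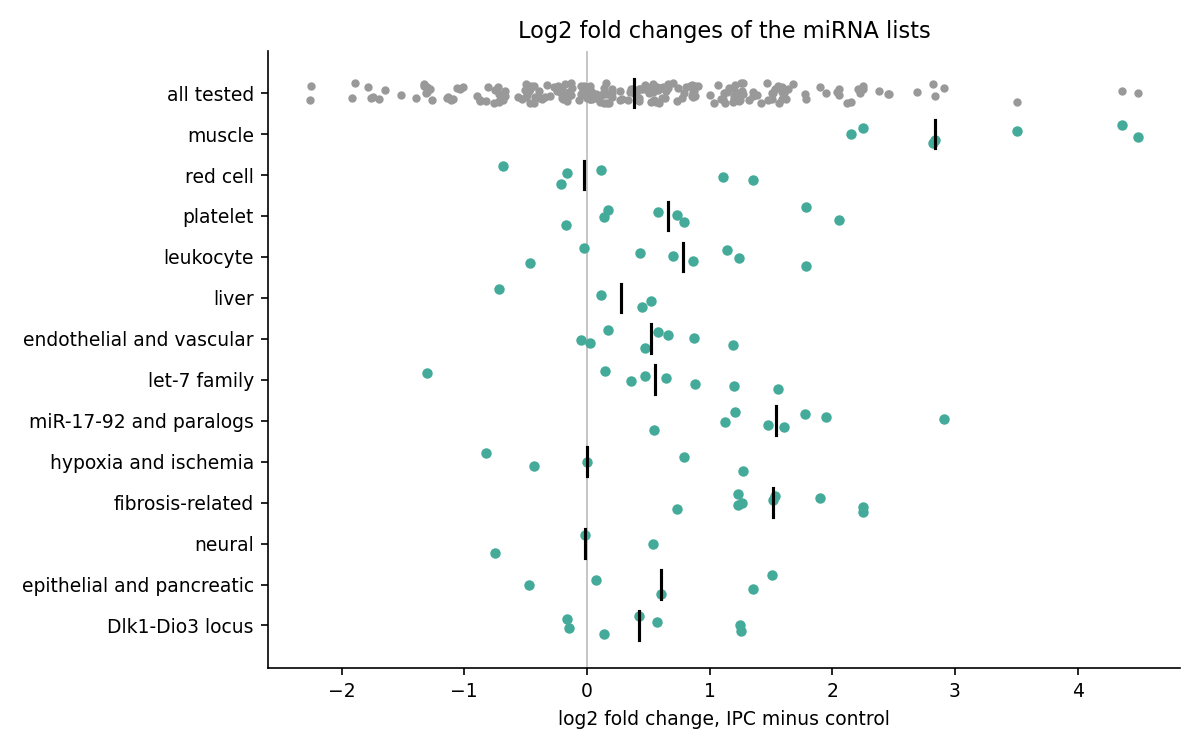
Log2 fold change (IPC minus control) of each tested miRNA, in grey for all 226 and in green for the members of each of the 13 lists, with black lines at the medians. The muscle list lies between 2.16 and 4.49, and the median of all tested miRNAs is 0.38.

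miR-148a-3p was the most abundant miRNA by mean CPM over all libraries, at 48803 ± 5089 normalised counts after IPC and 43148 ± 34059 in controls (n = 3 each). The rank did not hold in every library: in control replicate 3 it had 10091 recovered counts and miR-320-3p 28532. Together the 10 most abundant took 60.2% ± 6.50 of counts after IPC and 65.8% ± 6.62 in controls (exact permutation test, two-sided, p = 0.3). Besides those above, these were miR-378a-3p, miR-140-3p, miR-128-3p, miR-191a-5p, let-7i-5p and miR-423-5p, with log2 fold changes of -0.30 (SE 0.63), 0.56 (SE 0.59), -0.015 (SE 0.75), 0.14 (SE 0.79), 1.20 (SE 0.68) and -1.31 (SE 0.79). The sign for miR-191a-5p turns under 3 of the 4 other scalings. Without control replicate 2, miR-423-5p passed the adjusted threshold at -2.14, miR-128-3p was at -0.74 and miR-191a-5p at -0.60. miR-423-5p was at -0.71 without control replicate 3, and without control replicate 1 miR-191a-5p was at 0.95 and miR-148a-3p at 1.05. At least 10 counts were found for 256 ± 29.1 miRNAs in IPC libraries and 170 ± 29.4 in controls (exact permutation test, two-sided, p = 0.1), and for 170 ± 4.16 and 163 ± 20.5 after thinning every library to 111048 counts (p = 0.7 in the same exact test).

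In the authors' deposited table, 40 miRNAs had an unadjusted p below 0.05, 23 of them higher and 17 lower after IPC. The authors' deposited table gives miR-206-3p a log2 fold change of 4.42 (p = 6.8e-05) and miR-133a-3p 2.46 (p = 0.00221). Of the other tested muscle miRNAs, it gives miR-133a-5p 3.98, miR-133b-3p 2.32 and miR-1-3p 3.23 (authors' unadjusted p = 5.0e-04, 0.00429 and 0.00822). miR-1-3p was lower there than in limma, where it was at 4.36. So were the heart miRNAs, with miR-208a-3p at 1.79 and miR-499-5p at 1.77 against 2.83 and 2.82 in limma. The unadjusted p of these heart miRNAs in the authors' table was not below 0.05 (0.0735 and 0.0825). With Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 0 miRNAs passed 0.05 over the whole table (smallest 0.0516), and over the 480 with counts 1 passed, miR-206-3p (0.0324). Of those 40 miRNAs, 29 were tested here, 11 lay below the abundance filter, and 21 had an unadjusted p below 0.05 in limma.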

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

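The miRNAs below were singled out because they lay under the abundance filter of the comparison, had 0 counts in all 3 controls, and had at least 3 counts in every IPC library; this search was made after the data were seen. miR-18a-5p, a member of the miR-17-92 cluster, had 15, 32 and 23 counts in IPC replicates 1, 2 and 3, and was at least 5.72-fold higher than the 3 counts that 0 over the whole control group allow, after scaling to effective library sizes. miR-1839-3p had 8, 17 and 7 counts and was at least 2.61-fold higher, and miR-136-3p had 18, 8 and 6 counts and was also at least 2.61-fold higher. miR-200c-3p, miR-3542 and miR-19a-5p showed the same split, with bounds of 1.80, 1.80 and 1.47, under the 2-fold set for this search. The control libraries were shallower, and these bounds cover counting error only.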

How the results depend on the processing

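The thinned counts, the principal component covariate and the shortened lists were chosen after seeing the data. The counts of 0 miRNAs higher and 0 lower held under all scalings, the 10 CPM filter, both pseudocounts, an FDR of 0.1, limma-voom, thinning and the covariate. They became 3 higher with no filter on low counts (miR-206-3p, miR-1-3p and miR-18a-5p), and 2 higher (miR-206-3p and miR-1-3p) with sample quality weights. Leaving out each library gave 0 to 29 higher and 0 to 9 lower, and every call came without control replicate 2; the cause was not tested. By construction, the threshold of an unadjusted p below 0.05 and 2-fold gave 20 higher and 4 lower. With the replicate block 2 were higher (miR-206-3p and miR-1-3p), but the labels do not say that the numbers pair the samples. Deviations of same-numbered samples correlated at 0.13, -0.18 and -0.51, and not every sample correlated best with its own number. With 3 samples per group these correlations cannot show whether the samples are paired. The miR-133a-3p log2 fold change was positive under all 19 alternatives, 1.66 to 2.58 with a library left out and 1.86 to 2.51 otherwise. It passed the adjusted threshold without control replicate 2 alone (2.49, adjusted p = 0.0276; 0.0276 to 0.857 over alternatives). The 3 lists called became 0 with an estimated correlation and 2 to 3 with a library left out, and fry, which tests lists against no change, called 0. The muscle list kept its camera call in all 18 refits at an inter-gene correlation of 0.01. With the covariate the fibrosis-related and miR-17-92 lists lost theirs (camera, adjusted p = 0.431 for both). The muscle list was not the only list called with the covariate, since the total there stayed at 2 or more. The difference of 85.7 detected miRNAs became 7 after thinning, which ties it to depth, and was 73.5 to 102 with a library left out. Of 37 other named miRNAs, 10 had an unadjusted p below 0.05, with 0 sign changes in 188 refits. Of the other 27, 13 changed sign under some setting. The planned edgeR and DESeq2 fits were not run, on the deposited values or on the recovered counts, where limma-voom was the only model run. Depth limits the controls most: miR-206-3p rested on 3, 85 and 9 counts there.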

Other observations

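The comparisons of hairpin arms, the thinnings, the axis as a covariate, the ratio of muscle to heart miRNAs, the comparison of control replicate 2 with the IPC range, the neighbour test without the miR-17 clusters and the counts over splits were chosen after the results they bear on had been seen, and the miRNAs named here outside the rule were picked after their values. Over hairpins the 2 arms showed no common direction. Of 42 hairpins with both arms tested outside the muscle list, 17 had log2 fold changes of the same sign and 25 of opposite signs. The correlation of the arms over hairpins, which are not independent replicates, was -0.022. Signs of values near 0 are uncertain, such as -0.0040 for miR-378a-5p and -0.025 for miR-142-3p, since the median SE over the tested miRNAs was 0.79. miR-23a-3p was at 1401 ± 468 normalised counts after IPC and 488 ± 255 in controls (SD, n = 3 each), a log2 fold change of 1.64 (SE 0.69), and miR-23a-5p at 13.3 ± 12.3 and 56.2 ± 48.1, -1.91 (SE 0.93). miR-106b-5p and miR-106b-3p had log2 fold changes of 1.47 (SE 0.86) and -1.11 (SE 0.73). The arms of miR-872 went together, at 2.04 (SE 0.65) for 5p and 2.45 (SE 0.92) for 3p, as did those of miR-423, at -1.31 (SE 0.79) and -1.33 (SE 0.87). With all 6 libraries 0 of these passed the adjusted threshold in limma (adjusted p = 0.341 to 0.54), and without control replicate 2 the arms miR-23a-5p (-2.68), both of miR-872 (2.19 for 5p, 2.90 for 3p) and miR-423-5p (-2.14) did.

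Muscle miRNAs were higher after IPC, with a mean log2 fold change of 3.20 over the 7 tested (3.97 without control replicate 2, and 2.72 to 3.66 without any other library). Lower counts by themselves did not remove the rise. The 6 muscle miRNAs still tested after thinning to 111048 counts had a mean of 2.96 in 1 thinned fit with scaling recomputed. Their mean was 3.21 ± 0.0639 over 100 thinnings with fixed scaling (SD over thinnings), and 3.15 before. Random thinning keeps the expected shares of counts, so this mean could move little. It cannot test what made every IPC library deeper, which goes with the group and stays open. The library-wide axis cannot be told apart from IPC, since with it as a covariate the mean was 2.03 (SE 0.76, the list taken as 1 value per library with 3 residual degrees of freedom), 2 members and not 7 passed adjusted over the list alone, and the call in camera at a correlation of 0.01 (adjusted p = 4.3e-05) was absent with an estimated correlation (0.857), as without the covariate (0.68). Members went unlike ways with the covariate: miR-133a-5p was at 3.94 (SE 0.95), miR-206-3p at 3.12 (SE 0.96), miR-1-3p at 1.90 (SE 0.86), miR-133a-3p at 1.86 (SE 0.72) and miR-133b-3p at 1.74 (SE 0.76), while the heart miRNAs miR-208a-3p and miR-499-5p had a mean of 0.83, from 0.88 (SE 0.70) and 0.78 (SE 0.68), and for these the axis cannot be told apart from IPC either. Release from muscle opened by an operation cannot be told apart from ischemia of the heart either, since the labels give controls no sham operation. The log2 ratio of miR-206-3p to those heart miRNAs was 1.67 higher after IPC, with overlapping libraries (exact permutation test, two-sided, p = 0.3). Control replicate 3 alone made the overlap, at 2.15 against 0.94 to 3.50 after IPC. Control replicates 1 and 2 were at -0.59 and -0.20. The value of control replicate 3 rested on 9, 1 and 2 counts of miR-206-3p, miR-208a-3p and miR-499-5p, and that of control replicate 1 on 3, 4 and 6. With so few counts the ratio cannot decide this, and preconditioning itself stays open.

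Outside the muscle list, 1 axis took 59.8% of the variance over 219 miRNAs, and its loadings correlated with the log2 fold changes over miRNAs at 0.89. Lower counts by themselves did not shrink the axis. Thinning, which took the IPC libraries down 2.88- to 6.87-fold, left 106.4% ± 2.21 of the distance on it between the group means (SD over 100 thinnings). As for the muscle list, random thinning cannot test what made every IPC library deeper. A changed supply of whole hairpins would move both arms. The arms of 42 hairpins had loadings that correlated at 0.106 (95% bootstrap interval over hairpins -0.21 to 0.385). In the 21 hairpins whose weaker arm is more abundant it was 0.041 (-0.512 to 0.482). Few counts of a weaker arm, such as 15, 11 and 48 of miR-23a-5p in control replicates 1, 2 and 3, pull such a correlation towards 0. The correlation thus showed no common movement of the arms but does not decide this cause. A changed supply of primary transcripts, which would move both arms too, may contribute a part, since 74 pairs of miRNA genes within 10 kb had more alike loadings than permuted ones (mean absolute difference 0.0621 against 0.0766, permutation p = 0.029, one-sided), though p was 0.0708 without the miR-17 clusters and many neighbours are alike in sequence. Bias by sequence or RNA quality between libraries was not tested and stays open.

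Control replicate 2 lay with the IPC libraries on that axis, at 9.22 against 0.518 to 13.9 for IPC and -10.3 and -20 for the other controls. A mislabelled sample cannot be told apart from a control that differs by itself, since 2 of its 7 tested muscle miRNAs (miR-1-3p and miR-499-5p) lay within the range of the IPC libraries and the other 5 did not. Of those 5, miR-208a-3p lay just under that range. In control replicate 2, 6 of the 7 were above both other controls. Its total of 152343 counts goes with its label, near the other controls (111048 and 129728) and below the IPC libraries (319285 to 762927), but a total count excludes neither.

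The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. At an adjusted p below 0.05 in limma the real split gave 0 miRNAs and the highest other 25, and a count of 0 is met by 10 of 10 splits by construction, so this count decides nothing. At an unadjusted p below 0.05 the real split gave 24, the highest other 63, and 3 of 10 gave as many. For lists in camera the real split gave 3, the highest other 3, and 2 of 10 gave as many. The split with 25 and 63 set control replicate 2 with IPC replicates 2 and 3, which points to a structure of the samples, and a mislabelled control replicate 2 stays open there.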
